A study of Mus musculus with 8 samples.

How the data were processed

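Messenger RNA of lesional back skin was measured by bulk RNA sequencing in 8 female C57BL/6 mice, 4 in each of 2 groups, per the labels' protocols. Every mouse was 6 weeks old and received 5 nmol of MC903 on the back for 10 days. MC903 (calcipotriol) is a vitamin D analog that produces an inflammation resembling atopic dermatitis in mouse skin. One group then received 1 mM propionic acid, a short-chain fatty acid, 1 h after MC903, and the other a control application that the labels do not describe further. Skin was taken on day 11. Total RNA was extracted with TRIzol and 1 µg entered a VAHTS Universal V6 library, per the labels' protocols. The labels call the samples biological replicates, which is taken here to mean separate mice.

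The authors deposited 1 table with an FPKM value (fragments per kilobase of gene, scaled to library depth) for each of 25378 genes in each of the 8 libraries. Per the submitters' processing notes, the genome build was mm10 and the tools were CASAVA, cutadapt and HISAT2 2.1.0. The counting program, its strand setting and the gene annotation are not given in the sources used here. No gene in the table was at 0 in all 8 libraries. Without the strand setting, reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies are uncertain, since reads may have been split among copies. Those named below are Serpinb3a, Chil3, Chil4, Amy1 and members of the Sprr2 family.

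FPKM is not a count. Within a gene, however, the values in different libraries stood in whole-number steps after 1 factor per library. With a tolerance of 0.01 of a read, whole reads were recovered for all 25378 genes. The largest distance from a whole number was 0.00015 of a read. The recovered totals were 39034193 to 40194111 reads per library, and a tested gene had a median of 1224 recovered reads per library. A gene whose reads share a common divisor in all 8 libraries would be recovered too low. The relative value of 1 read ranged from 0.997 to 1.027 of that in control replicate 1.

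The design fixed before the data were examined allowed for counts or for normalized values, and the form for normalized values was used. DESeq2 and edgeR were not used, since the deposited values are not counts. Genes with an FPKM of 1 or more in at least 4 libraries were tested (12598 genes). Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with an intensity trend and robust moderation, group as the only term, 2-sided tests and Benjamini-Hochberg adjustment. Adjusted p in the text comes from this limma fit, and the threshold was 0.05. Fold changes on this scale understate the change of genes with low FPKM. Values are given as mean ± SD of FPKM, and a log2 fold change with its standard error (SE) or 95% confidence interval.

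In total 29 gene lists were fixed before the data were examined. They cover skin biology, the cell types and tissue parts that skin can hold, and RNA handling. Of 817 entries, 773 were matched in the table, and 28 lists with 5 or more tested members were used. The list of B and plasma cell genes had fewer and was not analysed here. Lists were tested with limma's camera, which compares a list with the other genes, with a preset correlation of 0.01 between genes and adjustment over the 28 lists. Camera with a correlation estimated from the data and limma's fry were alternatives. The fry test asks whether the members of a list move on balance one way, and its mixed form whether they change in either direction. Neither compares a list with other genes. For members of a list, the count that passes when p is adjusted over the list alone is also given. The mean log2 value of each list per mouse was compared with an exact permutation test over the 70 regroupings, whose smallest p is 0.0286.

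Genes were named by a rule fixed in advance. It takes up to 12 higher and 12 lower genes with the largest absolute log2 fold change among those past the threshold with a mean of 1 FPKM or more and no overlap between groups. With none past the threshold in a direction, it takes the 5 with the smallest p, without clone names. It also takes list members past the threshold, at most 4 per list and direction, and 12 genes whatever their values (Il33, Tslp, Il4, Il13, Ccl17, Flg, Lor, S100a8, Krt6a, Cyp24a1, Ffar2 and Hcar2). All other genes in the text were chosen after their values were seen. Gene positions are those of the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, matched by symbol.

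The limma step was checked on simulated data for the comparison of propionic acid with control. Reads were drawn from the real means and within-group spread of the tested genes, and 200 genes were changed in each of 5 simulations. About 12495 genes were tested per simulation. The step called 17.1% of the genes changed 1.5-fold, 60.4% of those changed 2-fold, 92.1% of those changed 4-fold and 97.5% of those changed 8-fold. False calls made up 5.9% of all calls. In a further simulation, a list of 25 genes shifted by 0.5 on the log2 scale was called, and 0 of 50 random lists were. The simulated genes varied independently, which real genes do not.

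Alternatives to the main settings were no filter on low values, a mean FPKM of 5 or more (of 1 or more for the lists), a pseudocount of 0.1, an added requirement of an absolute log2 fold change of 1, an adjusted p under 0.1, the replicate number as a block, the mean of the skeletal muscle list as a covariate, median-of-ratios scaling, and each mouse left out in turn. Chosen after seeing the data were quantile normalization, weights per library, voom on the recovered reads, control replicates 1 and 3 left out together, and the scaling and pseudocount alternatives where they had not been planned for that result. The labels give no sequencing batch, cage or harvest hour. KEGG pathways with 10 to 500 tested genes were tested by camera, and clock and Hox genes were examined, only after the data were seen. For the model-based counts, all 35 splits of the 8 samples into 4 and 4 were fitted in the same way.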

Results

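RNA was profiled in MC903-treated back skin of 8 mice, 4 given a control application and 4 given propionic acid. The comparison asks which genes differ between the lesions of the 2 groups. The deposited FPKM values summed to between 486414 and 566669 per library, and between 20330 and 21076 genes had a value above 0. Recovered totals lay between 39034193 and 40194111 reads, so depth was nearly equal across mice. The median Spearman correlation over tested genes was 0.967 for the 12 pairs within a group and 0.965 for the 16 pairs between groups.

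In the propionic acid group, the genes with the smallest p among those with higher values were Ucp3, Angptl4, Actn3, Npas2 and Fabp3. Ucp3, a mitochondrial carrier of muscle and fat, had 1.52 ± 0.982 FPKM in control skin and 10.8 ± 2.67 in propionic acid skin (SD, n = 4 each), a log2 fold change of 2.28 with an SE of 0.26. Angptl4, a secreted inhibitor of lipoprotein lipase, had 16.2 ± 4.75 and 54.1 ± 10.5 FPKM, a log2 fold change of 1.71 with an SE of 0.21. Fabp3, the heart-type fatty acid binding protein, had 13.6 ± 3.53 and 96.9 ± 68.3 FPKM, with 198.5 FPKM in propionic acid replicate 1. Actn3, an actinin of fast muscle fibres, had 39.5 ± 10.1 and 157.2 ± 58.9 FPKM, and Npas2, a transcription factor of the circadian clock, had 0.635 ± 0.111 and 1.73 ± 0.226. None of these 5 passed the threshold, and each had a limma adjusted p of 0.0998.

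Among genes with lower values in propionic acid skin, the smallest p belonged to Tef, Ch25h, Nr1d2, Cbln1 and Serpinb3a, and none passed the threshold. Tef and Nr1d2, both transcription factors with a daily rhythm, had 14.4 ± 2.08 and 16.4 ± 3.11 FPKM in control skin and 7.06 ± 0.844 and 8.02 ± 0.652 in propionic acid skin. Their log2 fold changes were -0.93 and -0.93, with SEs of 0.13 and 0.14. Ch25h, the cholesterol 25-hydroxylase, had 6.46 ± 0.855 and 3.01 ± 0.452 FPKM. Cbln1, a secreted protein best known from synapses, had 15.6 ± 14.2 and 0.917 ± 0.326 FPKM, with 36.7 FPKM in control replicate 3. The adjusted p was 0.0998 for these 4 genes. Serpinb3a, a serine protease inhibitor of keratinocytes with near-identical copies, had 52.1 ± 26.1 and 8.93 ± 5.10 FPKM (adjusted p = 0.159). For all 10 genes, the 4 control values and the 4 propionic acid values did not overlap.

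**Figure D1:**
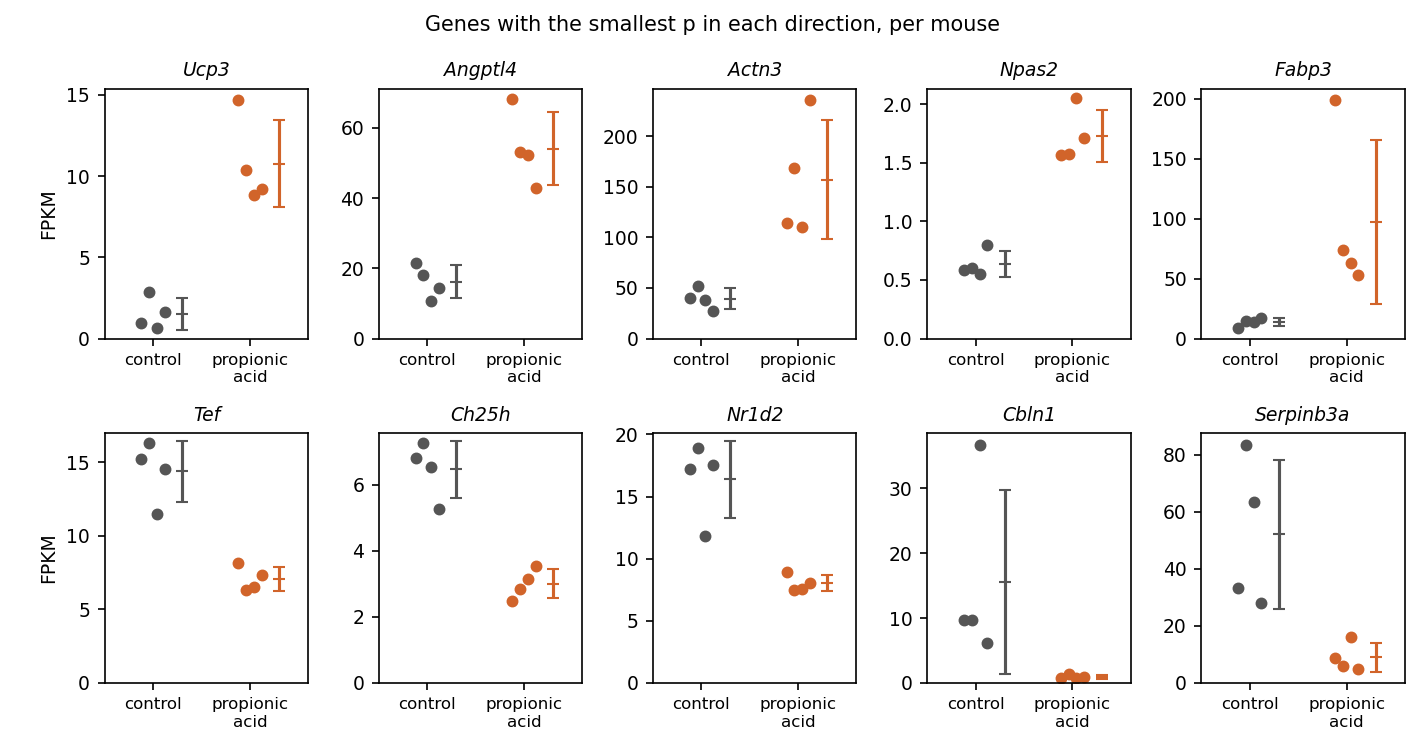
FPKM (vertical axis, linear from 0) of the 10 genes with the smallest p, 5 in each direction, 1 point per mouse in the control and the propionic acid group, with the mean and SD beside the points. The groups do not overlap in any panel, and Fabp3 reaches 198.5 FPKM in propionic acid replicate 1.

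In mm10, Ucp3 is at chromosome 7, 100472990 to 100486432, Angptl4 at chromosome 17, 33773750 to 33781830, and Fabp3 at chromosome 4, 130308595 to 130315463. Npas2 is at chromosome 1, 39193731 to 39363236, and Serpinb3a at chromosome 1, 107045587 to 107052303. Actn3 is at chromosome 19, 4861216 to 4877909, and Ch25h at chromosome 19, 34473778 to 34475164. Tef is at chromosome 15, 81802421 to 81826863, Nr1d2 at chromosome 14, 18204054 to 18239127, and Cbln1 at chromosome 8, 87468405 to 87472609. All 10 are annotated as protein-coding genes, and the FPKM values cover whole genes.

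Across the 12598 genes tested, 0 passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 792 genes, 513 higher and 279 lower with propionic acid, where chance alone gives about 630. The lean to higher values was smaller with median-of-ratios scaling (461 higher and 332 lower), quantile normalization (481 and 372) and weights per library (1038 and 878). With voom on the recovered reads, 0 genes passed the threshold and 765 had an unadjusted p under 0.05. With an adjusted p under 0.1 there were 13 genes, 9 higher and 4 lower. They are the genes above without Serpinb3a, together with Fbp2, Myh4, Mybpc2 and Amy1, which all had higher values and were chosen after their values were seen. The groups did not overlap for 397 genes (3.15%), and chance gives 2.86%. Without control replicate 2 the count past the threshold was 1 (Ucp3, adjusted p = 0.02), and without control replicate 3 it was 2 (Nr1d2, 0.0395, and Cbln1, 0.0209). The count at an unadjusted p under 0.05 was 1238 without control replicate 2, 442 without control replicate 3 and 524 without propionic acid replicate 1. It was 505 without both control replicates 1 and 3.

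Genes of fatty acid oxidation and targets of the PPAR nuclear receptors had higher values in propionic acid skin as a group. Of 25 tested members, 23 had a higher mean and 2 a lower one. The mean log2 fold change was 0.73 and the median 0.40, so some large rises lift the mean. Adjusted over the list alone, 16 members passed, all higher, and 9 did not, whereas 0 passed over all genes tested. Besides Ucp3, Angptl4 and Fabp3, those that rose by this measure included Pdk4, the kinase that inhibits pyruvate dehydrogenase, with 19.4 ± 13.3 FPKM in control and 141.3 ± 49.0 in propionic acid skin. Among enzymes of mitochondrial fatty acid oxidation, Hadhb had 15.7 ± 1.45 and 22.9 ± 3.45 FPKM, Acadvl 44.2 ± 2.95 and 58.8 ± 5.34, and Decr1 17.98 ± 1.97 and 26.0 ± 3.08. The receptors themselves did not pass. Ppara had 1.17 ± 0.420 and 1.04 ± 0.474 FPKM, Ppard 16.7 ± 3.62 and 15.4 ± 2.99, and Pparg 12.7 ± 1.74 and 13.4 ± 1.69. The list was called by camera (adjusted p = 4.75e-19) and by fry (adjusted p = 0.0493), but not with an estimated correlation (adjusted p = 0.338). The mean log2 value of the list was 4.37 ± 0.16 in control and 5.09 ± 0.19 in propionic acid skin (SD, n = 4), with an exact permutation p of 0.0286, the smallest possible, and 0.4 after adjustment over the lists. The call was kept with each mouse left out in turn. The adipocyte and skeletal muscle lists, described next, had higher means in the same samples.

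**Figure D2:**
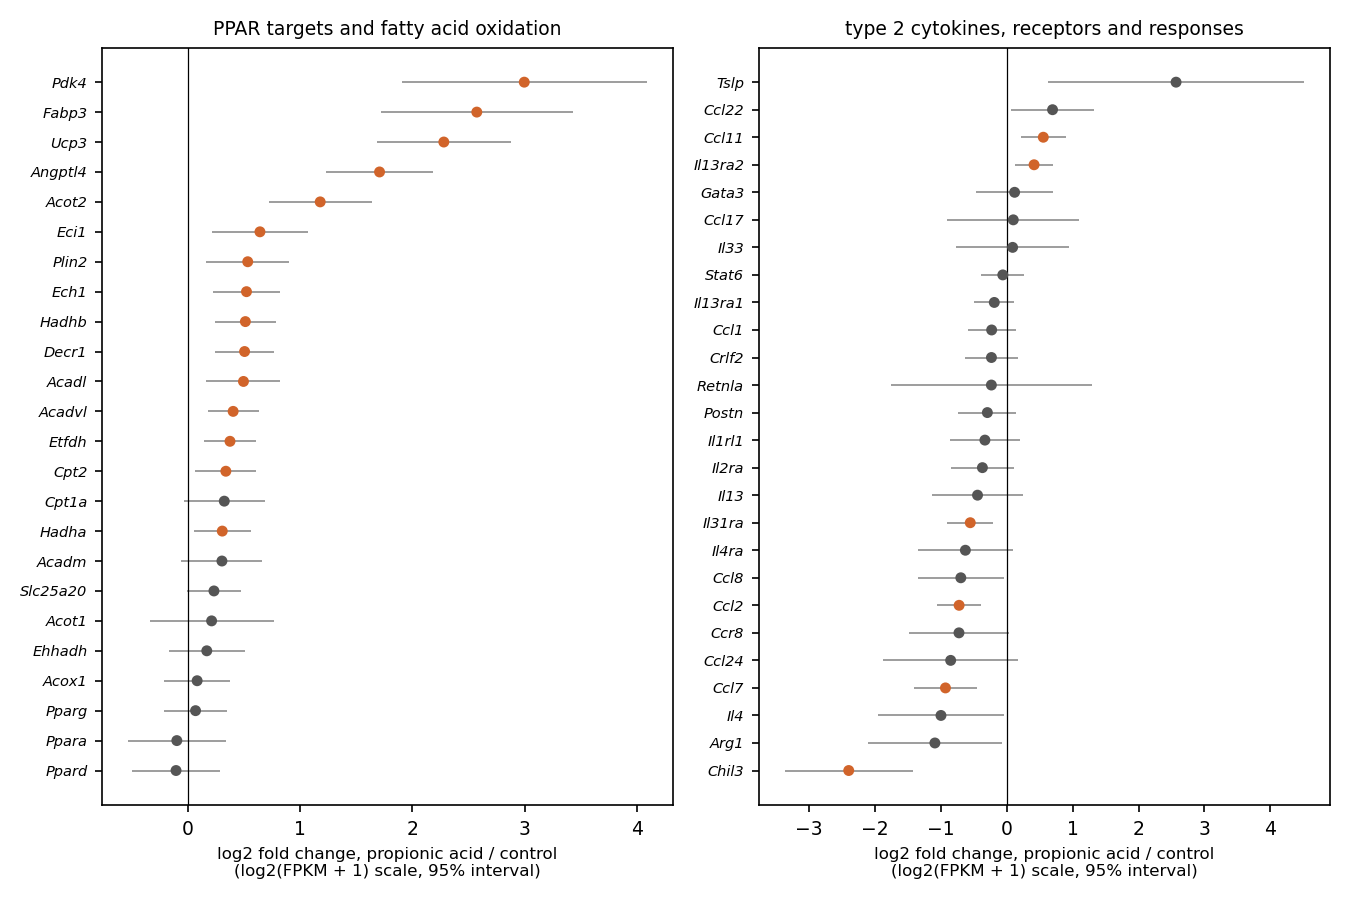
Log2 fold change of tested members of the fatty acid oxidation list (left, not all members drawn) and the type 2 list (right, all 26), propionic acid over control on the log2(FPKM + 1) scale, with 95% confidence intervals from limma. Orange points pass when p is adjusted over the list alone, all of them higher on the left, and 4 lower and 2 higher on the right.

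Some genes of fat cells, which lie below the dermis, had higher values in propionic acid skin. In the adipocyte list, 17 of 20 members had a higher mean, and 6 passed when adjusted over the list alone (all higher, 0 over all genes tested), while 14 did not. Among these, Pck1, which makes phosphoenolpyruvate, had 13.5 ± 1.59 and 67.1 ± 38.3 FPKM, Cidec, a lipid droplet protein, 90.8 ± 13.8 and 193.7 ± 49.1, and leptin (Lep) 0.656 ± 1.19 and 5.84 ± 3.20. Perilipin 1 (Plin1) did not pass, at 17.2 ± 17.3 and 23.0 ± 23.3 FPKM. The call by camera (adjusted p = 9.65e-08) was lost with an estimated correlation (adjusted p = 0.621). It was kept with each mouse left out in turn. Control replicate 1 stood apart on this list, with a mean log2 value of 5.739 against 4.877 to 4.99 in the other controls and 5.21 to 6.306 in propionic acid skin. The mean value of the list per mouse had an exact permutation p of 0.0857, and 0.4 after adjustment.

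Members of the skeletal muscle list went both ways. Of 27 tested, 19 had a higher and 8 a lower mean, and 6 higher and 2 lower members passed when adjusted over the list alone (0 over all genes tested), while 19 did not. Myh4, the myosin heavy chain of the fastest fibres, had 24.7 ± 18.1 FPKM in control and 222.9 ± 110.5 in propionic acid skin, and Mybpc2, a myosin binding protein of fast fibres, had 16.7 ± 6.08 and 66.7 ± 18.9. Myh1, another fast myosin heavy chain, was lower, at 417.1 ± 118.4 and 139.5 ± 90.3 FPKM, as was Mybpc1, the slow form of the binding protein, at 74.9 ± 11.6 and 43.8 ± 19.1. The abundant skeletal actin Acta1 did not pass, at 1507 ± 319.2 and 1404 ± 507.3 FPKM. The list was called by camera as higher (adjusted p = 0.00301), and the call was lost without propionic acid replicate 1 (adjusted p = 0.138) and with an estimated correlation (adjusted p = 0.621). In the mixed form of fry its adjusted p was 0.00761, and the mean value of the list per mouse had an exact permutation p of 0.0571 (0.4 after adjustment).

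Type 2 inflammation is the arm of immunity that marks atopic dermatitis. In this list, 19 of 26 members had a lower mean in propionic acid skin and 7 a higher one, with a mean log2 fold change of -0.28. Adjusted over the list alone, 4 lower and 2 higher members passed (0 over all genes tested). Lower were Chil3, a chitinase-like protein of macrophages with a close copy, with 66.0 ± 37.1 FPKM in control and 11.9 ± 7.92 in propionic acid skin, and the chemokines Ccl2 (58.7 ± 8.76 and 35.3 ± 5.87) and Ccl7 (137.5 ± 27.5 and 72.7 ± 20.04). Il31ra, a subunit of the receptor for the itch cytokine IL-31, was lower as well (2.96 ± 0.340 and 1.74 ± 0.557). Higher were the eosinophil chemokine Ccl11 (56.6 ± 9.57 and 83.5 ± 11.8) and Il13ra2, the decoy receptor of IL-13 (7.04 ± 1.18 and 9.69 ± 1.03). The list was called lower by camera (adjusted p = 2.30e-04), which was kept with each mouse left out in turn and lost with an estimated correlation (adjusted p = 0.569). The mean log2 value of the list was 4.844 and 4.876 in control replicates 1 and 3, which stand apart on the first principal component together with Chil3, against 4.589 and 4.468 in control replicates 2 and 4 and 4.147 to 4.563 in propionic acid skin. Without control replicates 1 and 3 the adjusted p was 0.0419.

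The cytokines named in advance did not pass. Tslp, the epithelial cytokine that MC903 induces, had 35.7 ± 40.2 FPKM in control and 170.4 ± 140.7 in propionic acid skin, a log2 fold change of 2.57 with an SE of 0.86 (adjusted p = 0.686). The Tslp log2 fold change was 1.979 without control replicate 2 and 2.071 without propionic acid replicate 4, and 3.266 without control replicate 4, which had 92.8 FPKM. Il33, another epithelial alarm cytokine, had 32.6 ± 15.4 and 32.0 ± 9.41 FPKM (adjusted p = 0.972). Il4 had 8.01 ± 4.37 and 3.42 ± 1.99 (adjusted p = 0.786), Il13 2.50 ± 1.23 and 1.57 ± 0.916 (adjusted p = 0.86), and the chemokine Ccl17 6.94 ± 5.54 and 6.63 ± 2.84 (adjusted p = 0.974). The 95% confidence interval of the log2 fold change was -0.76 to 0.94 for Il33 and -0.9 to 1.104 for Ccl17, so changes within these bounds are not excluded. It was 0.634 to 4.505 for Tslp, -1.945 to -0.043 for Il4 and -1.133 to 0.253 for Il13. These intervals are not adjusted for the number of genes tested. Without both control replicates 1 and 3, Il13 and Ccl17 turned direction, with log2 fold changes of 0.006 and -0.522, and those of Il33 and Il4 went from 0.09 to 0.677 and from -0.99 to -0.407.

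In the list of cornified envelope and terminal differentiation genes, 33 of 40 had a higher mean in propionic acid skin, and 0 passed when adjusted over the list alone. Flg (filaggrin) had 50.8 ± 35.3 and 54.3 ± 29.95 FPKM (adjusted p = 0.946), and loricrin (Lor) 346.4 ± 387.9 and 422 ± 277.9 (adjusted p = 0.89). The Lor log2 fold change of 0.83 became 1.55 without control replicate 2, which had 893.6 FPKM, and 0.247 without control replicate 1. In the list of activated keratinocyte and antimicrobial genes, 26 of 41 had a lower mean, and 1 member, Serpinb3a, passed when adjusted over the list alone. S100a8, an antimicrobial calcium-binding protein, had 147.2 ± 71.3 and 90.9 ± 65.8 FPKM (adjusted p = 0.852), and Krt6a, a keratin of activated epidermis, 1157 ± 611.2 and 1157 ± 325.3 (adjusted p = 0.97). Camera called the first list higher and the second lower (both adjusted p = 7.65e-04), and both calls were lost with an estimated correlation (adjusted p = 0.621). The mean values of the lists per mouse had exact permutation p values of 0.429 and 0.143. The first call was lost without control replicate 1 (adjusted p = 0.638) or propionic acid replicate 2 (0.0997), and the second without control replicate 2 (0.0961) or control replicate 3 (0.0959). Without both control replicates 1 and 3, which stand apart on the first principal component, the first list turned direction and was called lower (0.000969), as did Flg and Lor, with log2 fold changes of -0.707 and -0.662. Those of Krt6a and S100a8 went from 0.10 to 0.685 and from -0.80 to -0.253. With the skeletal muscle list as a covariate the second was also lost (0.0588).

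Camera called 9 further lists, all lower with propionic acid, and none of these calls held with an estimated correlation (adjusted p from 0.569 to 0.677). The estimated correlation between genes of these lists was 0.13 to 0.71, well above the preset 0.01, so the adjusted p values at the preset correlation are too small. In the list of itch receptors and nerve factors, 12 of 16 members had a lower mean (adjusted p = 7.65e-04), among them the substance P receptor Tacr1, with 4.43 ± 1.41 and 2.50 ± 0.709 FPKM. This call was kept with each mouse left out in turn. Interferon genes had a lower mean in 22 of 29 members (adjusted p = 7.65e-04), with Cxcl9, a T cell chemokine, at 26.0 ± 12.7 and 12.9 ± 2.095 FPKM. This call was lost without control replicate 1 (adjusted p = 0.487). Inflammatory cytokines and NF-kB targets were lower in 19 of 24 (adjusted p = 0.00544), which was lost without control replicate 3 (adjusted p = 0.232). Cell cycle genes were lower in 31 of 36 (adjusted p = 7.65e-04), which was lost without control replicate 1 (0.0742) or propionic acid replicate 1 (0.343). The interferon call was also lost with weights per library (0.101), and the cell cycle call with the muscle covariate (0.127). Without both control replicates 1 and 3 the interferon call was lost (0.297) and the inflammatory (0.931) and cell cycle (0.595) lists turned direction without a call. In these 4 lists, 0 members passed when adjusted over the list alone.

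The other 5 of these lists mark cell types. Basal keratinocyte genes were lower in 12 of 17 (adjusted p = 0.00608), which was lost without propionic acid replicate 3 (0.052). Endothelial and lymphatic genes were lower in 14 of 19 (adjusted p = 0.0103), which was lost without control replicate 1 (0.337) or propionic acid replicate 2 (0.349). Fibroblast and matrix genes were lower in 23 of 32 (adjusted p = 0.0229), which was lost without control replicate 1 (0.922), propionic acid replicate 1 (0.13) or propionic acid replicate 2 (0.309). Neutrophil genes were lower in 11 of 15 (adjusted p = 0.0188) and mast cell genes in 10 of 15 (adjusted p = 0.0229). In both lists Hdc, the enzyme that makes histamine, was the member that passed when adjusted over the list alone (43.7 ± 20.2 and 17.9 ± 2.92 FPKM). The neutrophil call was lost without control replicate 1 (0.052) or 3 (0.165) and without propionic acid replicate 2 (0.152), 3 (0.174) or 4 (0.0815). Propionic acid replicate 1 stood apart on this list, with a mean log2 value of 3.572 against 2.663 to 2.771 in the other mice of its group, and without it the adjusted p was 6.03e-08. The mast cell call was lost without control replicate 1 (0.052), control replicate 2 (0.354) or propionic acid replicate 1 (0.343). With the muscle covariate the fibroblast (0.124) and mast cell (0.0588) calls were lost and the basal keratinocyte list turned direction (0.98), and with weights per library the neutrophil call was lost (0.317). Without both control replicates 1 and 3 the neutrophil call was lost (0.931) and the fibroblast (0.132) and endothelial (0.858) lists turned direction without a call.

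**Figure D3:**
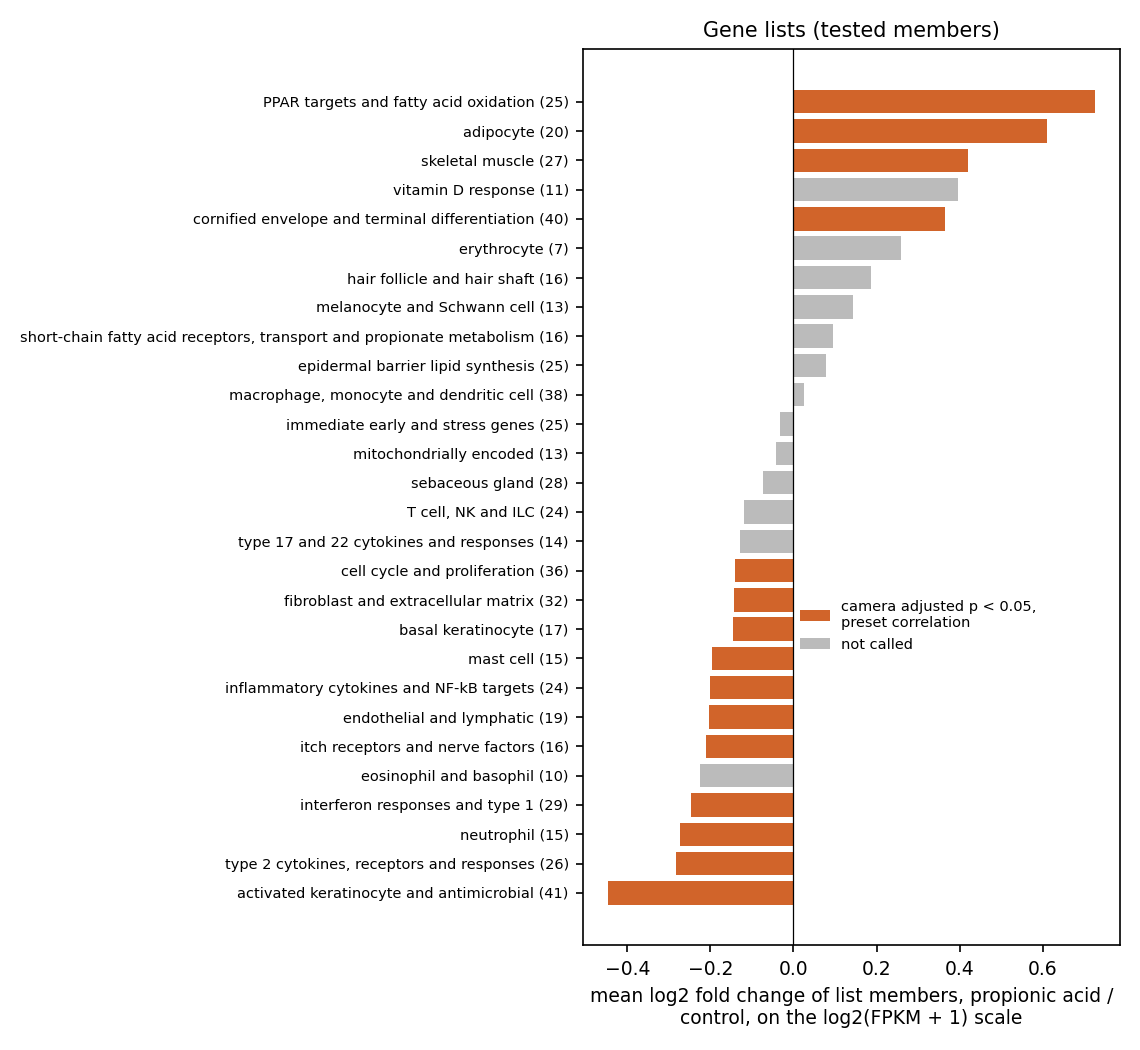
Mean log2 fold change of the tested members of each of the 28 lists, propionic acid over control on the log2(FPKM + 1) scale, with the number of tested members in brackets. Orange bars are lists called by camera with the preset correlation, 4 higher and 11 lower, of which 0 were called with an estimated correlation.

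The list of genes that sense, carry or break down short-chain fatty acids was not called. In this list, 9 of 16 members had a higher and 7 a lower mean (camera adjusted p = 0.29). Ffar2, a receptor for propionate, had 1.27 ± 1.04 and 2.07 ± 1.26 FPKM (adjusted p = 0.865), and Hcar2, the niacin and butyrate receptor, 20.1 ± 3.40 and 18.03 ± 2.22 (adjusted p = 0.887). Without both control replicates 1 and 3 the log2 fold change of Ffar2 went from 0.47 to 0.992 and that of Hcar2 from -0.14 to -0.34. Acss1, a mitochondrial acyl-CoA synthetase for short-chain acids, was the member that passed when adjusted over the list alone, with 4.22 ± 0.874 and 7.88 ± 1.18 FPKM. In the vitamin D list (camera adjusted p = 0.584), Cyp24a1, the enzyme that breaks down vitamin D and its analogs, had 336 ± 163.4 and 653.5 ± 343.7 FPKM (adjusted p = 0.797). The calcium-binding protein S100g passed when adjusted over the list alone, with 1.14 ± 0.394 and 5.59 ± 2.45 FPKM.

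The remaining 11 lists were not called. Camera gave an adjusted p of 0.104 for erythrocyte genes, 0.112 for eosinophil and basophil genes, 0.118 for type 17 and 22 cytokines, 0.149 for hair follicle genes, 0.177 for T cell, NK and ILC genes and 0.197 for melanocyte and Schwann cell genes. It gave 0.492 for sebaceous gland genes, 0.584 for macrophage, monocyte and dendritic cell genes, 0.797 for mitochondrially encoded genes, and 0.839 both for immediate early and stress genes and for barrier lipid synthesis. In the eosinophil and basophil list, Alox15 was higher and passed when adjusted over the list alone (0.938 ± 0.164 and 1.84 ± 0.418 FPKM). In the macrophage list the median log2 fold change was -0.08 and the test pointed down, whereas the mean was above 0. In the immediate early list the mean was -0.03, whereas the median was 0.05 and the test pointed up. In the comparison of mean list values per mouse, 0 of the 28 lists passed the exact permutation test after adjustment, and 1, the fatty acid oxidation list, passed before it.

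The first principal component of the 500 most variable tested genes held 44.3% of their variance and the second 18.4%. Control replicates 1 and 3 lay at the negative end of the first component, at -18.62 and -20.18, and control replicates 2 and 4 at 4.69 and 2.65. Propionic acid samples lay between -2.09 and 15.59. Genes at the negative end included Chil4, Saa3, Gzmb, Sprr2f, Cbln1 and Serpinb3a. Those at the positive end included Krt77, Krt10, Lor, Pdk4 and Fabp3. Not every gene at the negative end was highest in both control replicates 1 and 3. Serpinb3a was highest in control replicate 2 (83.54 FPKM, against 33.36 in control replicate 1). Cbln1 was highest in control replicate 3 (36.72) and alike in control replicates 1 and 2 (9.684 and 9.704). On the second component, controls lay between -3.44 and 14.6 and propionic acid samples between -10.43 and 0.19, so the groups overlap. Genes at its negative end included Myh4, Tslp, Lep and Fabp3, and those at its positive end Serpinb3a, Cbln1 and Chil3.

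**Figure D4:**
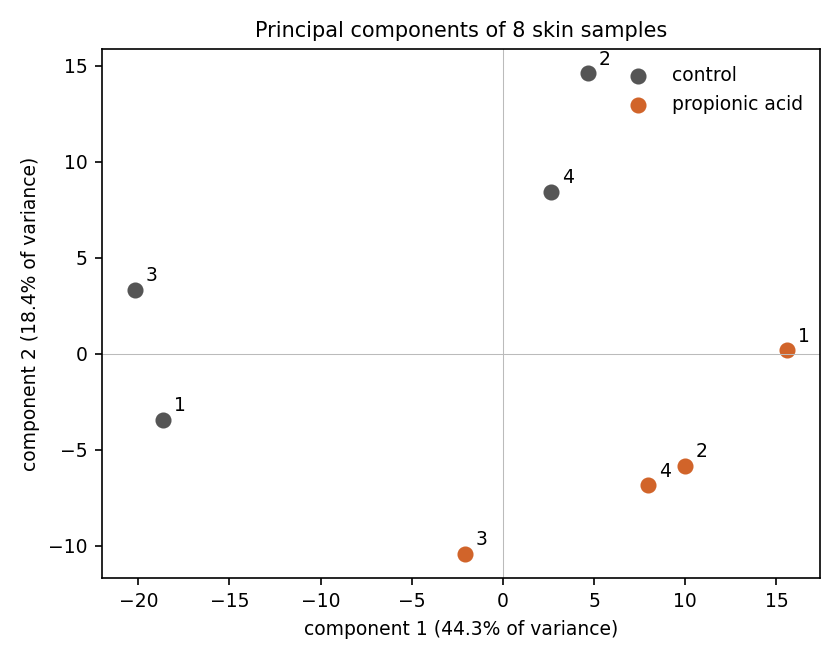
First component (horizontal axis, 44.3% of variance) against the second (vertical axis, 18.4%) of the 500 most variable tested genes, 1 point per mouse in the control and the propionic acid group, numbered by replicate. Control replicates 1 and 3 lie at -18.62 and -20.18 on the first component, apart from the other mice.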

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

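A single mouse far from the other 3 of its group was seen in 5 of the 114 groups of values tested, with Dixon's ratio of gap to range above 0.829. Chance gives about 5.7, so these are no more than chance gives, and no explanation was tested. In propionic acid replicate 1, Fabp3 was at 198.5 FPKM against 52.72 to 73.4 in the other mice of the group (ratio 0.858). In control replicate 3, Cbln1 was at 36.72 FPKM against 6.121 to 9.704 (ratio 0.883). The mean log2 value of the immediate early and stress list was 5.348 in control replicate 1 against 5.997 to 6.075 (ratio 0.893). That of the adipocyte list was 5.739 in the same mouse against 4.877 to 4.99 (ratio 0.869). That of the neutrophil list was 3.572 in propionic acid replicate 1 against 2.663 to 2.771 (ratio 0.881).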

How the results depend on the processing

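The weights per library, quantile normalization, voom, control replicates 1 and 3 left out together, the estimated correlation within the replicate block, and all alternatives for the count at an unadjusted p under 0.05 were chosen after seeing the data. The number of genes past the threshold, 0 in limma, was 1 with weights per library, 13 with an adjusted p under 0.1, and 0 to 2 with each mouse left out. It stayed at 0 under the other alternatives. The 792 genes at an unadjusted p under 0.05 became 1351 with no filter, 496 with a mean FPKM of 5 or more, which tests fewer genes, 1916 with weights per library, 505 without control replicates 1 and 3, and 442 to 1238 with each mouse left out. The 15 lists called became 0 with an estimated correlation, 0 with it in the replicate block, and 1 with fry. With each mouse left out 4 of the 15 calls were kept every time, and 4 were kept in all 10 other alternatives that use the preset correlation. With the skeletal muscle covariate, the basal keratinocyte list (adjusted p = 0.98) and, by construction, the skeletal muscle list (0.124) reversed. Without control replicates 1 and 3 the lists of cornified envelope (0.000969), inflammatory (0.931), cell cycle (0.595), fibroblast (0.132) and endothelial (0.858) genes reversed, as did the log2 fold changes of Il13 (0.006), Ccl17 (-0.522), Flg (-0.707) and Lor (-0.662). Other genes reversed too. With weights per library the log2 fold change was -0.19 for Il33 and -0.22 for Krt6a, with quantile normalization -0.01 for Krt6a, and with the muscle covariate -0.697 for Ccl17. With each mouse left out it ranged from -0.31 to 0.312 for Il33, from 1.979 to 3.266 for Tslp, from 0.247 to 1.55 for Lor, from 0.218 to 0.734 for Ffar2, from -1.339 to -0.725 for Il4, from -0.652 to -0.252 for Il13, from -1.221 to -0.484 for S100a8, from -0.231 to -0.062 for Hcar2, from 0.648 to 1.202 for Cyp24a1, from -0.235 to 0.518 for Ccl17, from -0.137 to 0.617 for Flg and from -0.113 to 0.404 for Krt6a. Except where the construction is named, the cause was not tested. The replicate numbers gave no clear sign of pairing, with deviations from the group mean correlating between mice of the same number at -0.319, -0.081, 0.2 and -0.117. Such values cannot exclude a link between mice of the same number, on which the labels are silent. The alternatives that need deposited counts (DESeq2, voom with quality weights, edgeR scalings) were not run. At this spread, 1.5-fold changes were called in 17.1% of simulated cases. There, 200 genes were changed in each simulation and genes varied independently, so this share need not hold for the real samples.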

Other observations

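Genes of the circadian clock and Hox genes, which mark position along the body, were examined after values of some of them were seen. Their counts are therefore not independent evidence. Of 16 clock genes, 11 passed when adjusted over the list alone, and 0 over all genes tested. Dbp, an output gene of the clock, had 11.7 ± 5.62 and 2.63 ± 0.733 FPKM in control and propionic acid skin (SD, n = 4), Per1 12.9 ± 4.07 and 5.89 ± 0.787, and Arntl, which encodes the clock activator BMAL1, 1.12 ± 0.169 and 1.98 ± 0.260. Nr1d1, another clock repressor, did not pass, at 19.6 ± 6.51 and 18.2 ± 2.64. Of 23 Hox genes 18 were tested, and 3 passed when adjusted over the list alone (0 over all genes tested), in both directions. Hoxc10 had 3.75 ± 2.19 and 0.398 ± 0.761 FPKM, with 0.6022 in control replicate 3 against 4.047 to 5.634 in the other controls, and 1.54 in propionic acid replicate 1 against at most 0.0527 in the others of its group. Hoxb9 had 2.73 ± 0.673 and 1.15 ± 0.432 FPKM, and Hoxc6 3.03 ± 0.176 and 5.02 ± 1.12.

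KEGG pathways were tested after the data were seen. Camera called 47 of 321, 13 higher and 34 lower, and 0 with an estimated correlation (lowest adjusted p = 0.955) or with fry. The smallest p belonged to PPAR signaling (58 genes, higher, adjusted p = 0.00155), which overlaps in content with the fatty acid oxidation list. Fatty acid degradation (36 genes) was higher and focal adhesion (173 genes) lower, both at an adjusted p of 0.00361. Propanoate metabolism (29 genes) was also called higher by camera (adjusted p = 0.0399), unlike the list of short-chain fatty acid genes above.

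Of the tests that follow, all except the first 3 counts of splits were chosen after the result was seen. The samples can be split into 4 and 4 in 35 ways. For genes past the threshold, all 35 give as many as the real split (0, highest other 0), which a count of 0 makes certain, so this tests nothing. For genes at an unadjusted p under 0.05, 9 of 35 splits gave as many (792, highest other 3275), and for lists called, 9 of 35 (15, highest other 17), so chance is not excluded for either. Every split called at least 5 lists, so camera calls at the preset correlation arise here under any grouping of the mice. The split with 3275 genes set control replicates 1, 3 and 4 with propionic acid replicate 3 apart from the rest. It calls several times the real count, which points to a structure of the samples. The mice it sets apart are those with the lowest values on the first principal component. They lay at -20.18 to 2.65, and the rest at 4.69 to 15.59. What drives that component was not tested.

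The fatty acid oxidation list was called higher with propionic acid at the preset correlation but not with an estimated one (adjusted p = 0.338), and for this list 1 of 35 splits, the real one, gave so small a camera p (as -log10 p 19.77, highest other 11.988), but it was picked as the list with the smallest p of 28, and in 4 of 35 splits some list had as small a p (highest other 24.989), so chance is not excluded. Whether more skeletal muscle was the whole cause is not decided. With the muscle list mean as a covariate, the mean log2 fold change of the list was 0.69 (0.6 to 0.77 with each mouse left out). Without it, the value was 0.73 (0.64 to 0.79). The muscle list mean had an SD of 0.109 in control and 0.389 in propionic acid skin, so the latter mice largely set this adjustment. It also averages members that went both ways, such as Myh4 and Myh1, and may track the amount of muscle poorly. More fat as the whole cause is argued against, and only for the list mean, with 0.77 (0.7 to 0.84) when the adipocyte list mean is the covariate. With an estimated correlation, however, camera did not call the list with either covariate (adjusted p = 0.758 for muscle and 0.44 for fat). Muscle and fat were not fitted together, so a part played by either, or by both at once, is not excluded. These covariate tests were chosen after an earlier one did not decide, in which the 10 most abundant muscle genes had a median log2 fold change of 0.3 (0.08 to 0.51) and the 10 most abundant fat genes 0.39 (0.34 to 0.68), against a list median of 0.4 (0.34 to 0.45). Chance, more skeletal muscle, propionic acid itself, a difference in feeding or harvest hour, and skin taken from another position along the back stay open.

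In the clock genes, the mean of evening genes minus that of morning genes was 0.72 ± 0.31 in control and -0.26 ± 0.22 in propionic acid skin (SD, n = 4), a difference of -0.98 (-1.11 to -0.86 with each mouse left out). Npas2, Tef and Nr1d2, whose small p led to the set, are part of it, so no test of the difference is given. A different harvest hour or feeding state of the groups cannot be told apart from an effect of propionic acid, because the labels give neither the hour nor the feeding of each mouse.

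The fast muscle fibre genes Myh4, Actn3 and Mybpc2 had higher values with propionic acid (limma adjusted p = 0.0998 each, not past the threshold). Myh1, another fast fibre gene, had lower ones. Whether more skeletal muscle was the cause is not decided. The 10 most abundant muscle genes had a median log2 fold change of 0.3 (0.08 to 0.51 with each mouse left out). Each of the 3 genes had at least 1.93 (1.67 to 2.07), but they were named for their small p, which favours such a gap. Of the 10, Myh1 (-1.75) and Acta1 (-0.15) were lower, and the others were higher, from 0.02 for Tcap to 1.52 for Pvalb. Skin taken from another position along the back cannot be told apart from an effect of propionic acid, because position is not in the labels. The posterior minus anterior Hox score was 0.17 ± 0.36 in control and -0.63 ± 0.28 in propionic acid skin, a difference of -0.8 (-0.97 to -0.68 with each mouse left out), but the groups overlap, with control replicate 3 at -0.34 and propionic acid replicate 1 at -0.2, and these genes too were chosen after values were seen.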
